A study of Homo sapiens with 5 samples.

How the data were processed

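The series holds single-cell RNA libraries of colonic lamina propria from 5 human subjects with active ulcerative colitis, 1 library per subject. Per the labels' protocols the tissue was cryopreserved and thawed, its epithelial layer was removed with EDTA, and the rest was digested with enzymes before cells were captured. The deposited library tables hold UMI counts per gene and cell barcode (unit: counts), 4000 barcodes in each of libraries 1 to 3 and 10000 in each of libraries 4 and 5, 22501236 UMIs in all. The authors also deposited a processed table of 20805 genes and 3979 cells whose unit is a score: each gene is centred and scaled over all cells, with a highest value of 10. The score equals, within rounding, the same scaling of ln(1 + UMIs per 10000) computed from the counts. Per the submitters' processing notes, bcl2fastq, Seurat 3.1 and the hg19 build were used. The aligner, its settings and the limits on cells were not given in the sources used here. In the values, kept cells had 203 to 2497 genes and at most 15.05% mitochondrial UMIs. No column of the tables was left unused. XIST and Y-linked genes were dropped on loading.

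The cells were those of the processed table and the values were their UMI counts. Cells were clustered with scanpy 1.11.5 on 2000 variable genes. Left out of these were all genes of the held-out lists named below, immunoglobulin genes, T cell receptor segments, mitochondrial and ribosomal genes, and XIST and Y-linked genes. Counts were scaled to 10000 per cell and logged, the library mean per gene was removed, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1 followed. A cluster in which no lineage held 85% of the cells with a lineage call was split within each library on 1000 variable genes and 10 components, a step added after the clusters had been seen to mix lineages. A cluster took the class whose markers were raised most, with at least 3 of them more than 2-fold above the library's other cells. It stayed unnamed where its 10 leading genes held at least 1 marker of another class and as many of that class as of its own, where it held none of its own and its median UMIs were under 33% of the library's, or where it held fewer than 5 cells. The tie clause was tightened after the isotype values had been seen, and the earlier naming is among the alternatives. Names such as T-like rest on RNA alone. Doublets were called with scrublet per library (117 of 3979 cells, 2.94%) and removed in an alternative only, in which the remaining cells were clustered and named anew, so that removal and naming changed together.

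UMIs were summed per library and class. Classes with at least 20 cells in at least 3 libraries entered an edgeR 4.0.16 fit in R 4.3.3, with TMM scaling, filterByExpr, a library block and the robust quasi-likelihood test. Each class was tested against the mean of the others. An SE beside a log2 difference was its absolute value divided by the square root of the test's F, and is not a spread between libraries. Benjamini-Hochberg adjustment ran over all genes and classes with a threshold of 0.05, and again over the listed genes alone. Held-out lists covered T cell activation and checkpoints, MHC class II, drug targets, homing, inflammatory mediators, interferon-stimulated genes, stress and dissociation, type 1 effectors and type 17 genes.

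T-like cells with a KLRB1 UMI were set against as many without, matched on total UMIs within the library, and the same test was run with a library block and without KLRB1. Plasma-like cells with at least 10 heavy-chain constant UMIs, at least 80% of them IgG or IgA, were compared in the same way without immunoglobulin genes. Both comparisons took libraries with at least 20 cells on each side. Gene lists with at least 4 tested members were tested with camera, at a preset correlation of 0.01 and with an estimated correlation, and with fry, on voom values (limma 3.58.1). The test of HLA-DRA with CD38 was a Mantel-Haenszel log odds ratio over 10 UMI strata per library with 0.5 added to its numerator and denominator, and an exact sign-flip test over libraries. The same sign-flip test served IL17A. Shares carry exact Clopper-Pearson intervals at 95%. A count of 0 was taken to allow 3 counts. Comparisons, tests, lists and the rule for naming genes were fixed before the data were examined, except where stated.

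The text names up to 4 genes per list and class with the largest fold past the threshold, some of which were left out where 1 library decided the call. For the KLRB1 and isotype comparisons it names up to 10 genes in each direction with an average log2 CPM (UMIs scaled to a common library size) of at least 5 and the same direction in every library, and a fixed set of cytokine and drug-target genes. The genes IGHG1, IGHA1, IGKC and AL928768.3 fall outside this rule and were named after their values were seen. Gene positions came from the GENCODE 44 annotation placed on GRCh37.

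Median UMIs per cell were 1682, 2146, 1723.5, 589 and 918 in libraries 1 to 5, and median genes 927, 1016, 960, 386.5 and 572. Each library came from a separate subject and counted as 1 sample. Each fit was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. The class fit (3113 genes) called 41 and 81 of them in the right direction with 1 false call, the KLRB1 fit (3110 genes) 40 and 80 with 2 false calls, and the isotype fit (3905 genes) 49 and 76 with 4 false calls. The simulated counts had the same dispersion for all genes and, before the changes, the same means in every class of a library. The class fit was read for T-like cells only. The false calls thus do not give the error rate of the real fits.

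Alternatives were DESeq2 1.42.0's Wald test, its size factors in edgeR, no low-count filter, no library block, each library left out in turn, profiles of at least 10 cells, and a filter of at least 300 genes, 500 UMIs and at most 20% mitochondrial UMIs in place of the authors' cells (4840 cells, 3692 of them shared). Further alternatives were removal of called doublets, Leiden resolution 0.5, and all KLRB1-negative T-like cells or another seed of the matching. Isotype purity of 95%, at least 3 heavy-chain UMIs, and cells thinned to 500 UMIs were also run. In another alternative IgA and IgG cells were matched on depth within the library, with the larger side cut to the size of the smaller. Alternatives chosen after seeing the data were immunoglobulin genes left out, T-like cells with at least 10 heavy-chain UMIs left out, libraries 4 and 5 left out, classes named cell by cell and the earlier naming of tied clusters. The planned pairs of classes within the T and the myeloid lineage, such as regulatory against other T cells, were left out because none of them had enough cells. B-like against plasma-like cells was not among the planned pairs and was not run. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.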

Results

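The labels describe colonic lamina propria, the immune-rich connective tissue under the gut epithelium, from 5 human subjects with active ulcerative colitis, a chronic inflammation of the colon. The series title asks how the immune cells of ulcerative colitis and of Crohn's disease differ. All 5 libraries of single-cell RNA carry the same labels, so the series holds 1 group without control tissue and nothing here compares disease with health. The libraries held 9168476, 4837301, 6060840, 1040991 and 1393628 UMIs (unique molecular identifiers, counts of captured RNA molecules). The deposited processed table kept 1754, 227, 1326, 448 and 224 cells of libraries 1 to 5, at medians of 1682, 2146, 1723.5, 589 and 918 UMIs per cell. Libraries 4 and 5 were the shallowest. Intervals and limits below cover counting error only.

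T-like, B-like and plasma-like cells held the largest mean shares of the 3979 cells. T-like cells, the lymphocytes that bear the T cell receptor, made up 25.5% ± 11.1 (SD, n = 5 libraries), and B-like cells, their antibody-lineage counterparts, 20.9% ± 16.1 (SD, n = 5). Plasma-like cells, which secrete antibody, made up 19.3% ± 16.1 (SD, n = 5) and ranged from 0.446% of the cells in library 5 (1 of 224) to 42.0% in library 1. The value of library 5 rests on the naming of a tied cluster: it was 11.2% (25 cells) when tied clusters kept their name, 12.8% with called doublets removed and cells clustered anew, and 14.8% with cells by the other filter. Fibroblast-like cells, which lay down the tissue matrix, made up 9.93% ± 9.42 (SD, n = 5) and endothelial-like cells, which line vessels, 7.05% ± 5.11 (SD, n = 5). Macrophage-like or monocyte-like cells made up 4.34% ± 5.10 (SD, n = 5), or a mean of 2.13% without library 2. Epithelial-like cells made up 4.32% ± 4.32 (SD, n = 5), or 2.60% without library 1, in tissue whose epithelial layer had been removed with EDTA per the labels. Pericyte-like or smooth muscle-like cells made up 1.77% ± 2.59 (SD, n = 5), or 0.781% without library 2. The 93 cells named NK-like, for the cytotoxic innate lymphocytes, all came from library 1, so their mean share of 1.06% ± 2.37 (SD, n = 5) was 0 without it. In libraries 2, 3 and 4 the count of 0 comes from the naming rule: 4, 3 and 3 of their cells fell in the same cluster, with GZMB among their leading genes, and were too few to be named. No cell of library 5 fell in that cluster. Of the 93 cells 31 had CD8A and CD8B among their leading genes, so cytotoxic T cells are not parted from NK cells here. Cells in clusters that met no naming rule made up 5.80% ± 4.76 (SD, n = 5). With 1 group, no share was tested against another condition.

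**Figure D1:**
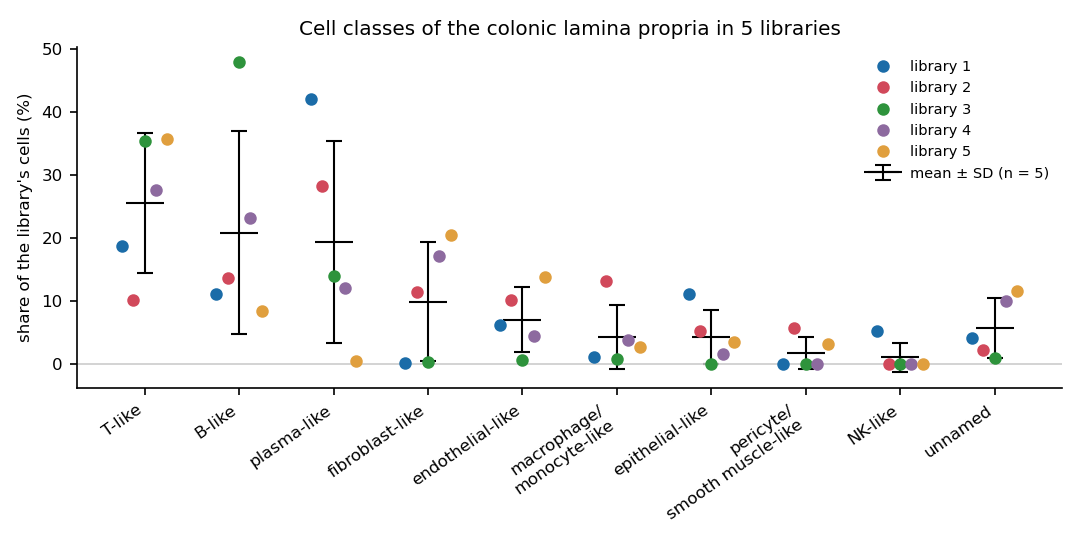
Share of each library's cells (percent, vertical axis) by cell class (horizontal axis); points are the 5 libraries, and black lines with whiskers give the mean and SD. T-like cells lie between 10.1% and 35.7% in all 5 libraries, and B-like cells between 8.48% and 47.8%.

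Genes of inflammation and of colitis drugs divided by cell class. Each of 5 classes was compared with the mean of the other 4 in the 127 genes of the held-out lists, which had been kept out of the clustering, and 69 of them had enough UMIs to test. Among these 5 classes T-like cells held more RNA of checkpoint receptors, cytotoxic and type 17 genes. B-like cells held more of MHC class II, the molecules that present peptides to helper T cells. TNF, the cytokine that infliximab and adalimumab bind, was higher in both. NK-like and macrophage-like or monocyte-like cells had too few libraries to enter. The genes are thus not shown to be confined to T-like or B-like cells. Leading genes of the NK-like clusters of library 1 included GZMA, GZMB and CCL5. In that library TNF stood at 182 CPM in NK-like, 124 in T-like and 224 in B-like cells. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all 3113 genes called 148 of 345 gene and class pairs, 88 higher and 60 lower, and 181 pairs had an unadjusted p under 0.05. The T-like profiles came from 5 libraries, the B-like, plasma-like and endothelial-like profiles from 4 each and the fibroblast-like profiles from 3. Without library 1 the calls were 93, whereas without libraries 2, 3, 4 and 5 they were 131, 130, 188 and 155.

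T-like cells were higher in 31 and lower in 12 of the 69 genes (31 and 13 adjusted over the list alone). The higher genes took in 10 of 12 tested members of the activation and checkpoint list, 4 of 4 of the type 1 and cytotoxic list, 2 of 2 of the type 17 list, 8 of 9 of the homing and residency list and 4 of 8 drug targets. Of the 12 members each of the type 1 and type 17 lists only 4 and 2 had enough UMIs to test. A gene could pass the low-count filter through the T-like profiles alone, so these counts were set in part by the filter. CTLA4, the inhibitory receptor that competes with CD28 for its ligands, was higher by a log2 difference of 5.50 ± 0.39 (SE, n = 5 libraries; edgeR, Benjamini-Hochberg adjusted p = 2.82e-11), and stood at 467 ± 150 CPM (UMIs of the gene scaled to a common library size; SD, n = 5). GZMA and GZMB, proteases of cytotoxic granules, were higher by 5.23 and 3.20, and CCL20, a chemokine that draws cells bearing CCR6, by 4.55 ± 0.45 (SE). KLRB1, whose protein CD161 marks memory T cells with a type 17 programme, was higher by 4.18 ± 0.43 (SE). ICOS, LAG3, TNFRSF18 and IFNG stood at 388 ± 196, 328 ± 365, 240 ± 158 and 258 ± 183 CPM (SD, n = 5), with LAG3 from 16.9 in library 2 to 833 in library 1. These 4 genes had 0 UMIs in the fibroblast-like profiles, so their fitted folds depend on the prior count and are no bound. IFNG, the type 1 cytokine, passed edgeR's test with a Benjamini-Hochberg adjusted p = 1.18e-08, and CCL5, at 355 ± 238 (SD, n = 5) and 0 in the endothelial-like profiles, with an adjusted p = 9.60e-06.

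The homing genes CCR7, GPR183 and CXCR4 were higher in T-like cells by log2 differences of 2.71, 2.33 and 2.25. ITGA4 and ITGB7, the chains of the gut-homing integrin that vedolizumab blocks, were higher by 1.79 and 1.37, and JAK3, a kinase that tofacitinib inhibits, by 0.96, a call lost without library 1 at the same 0.96. TNF was higher by 3.03 ± 0.45 (SE; edgeR, Benjamini-Hochberg adjusted p = 3.98e-06). Among 9 interferon-stimulated genes 3 were higher and 1 lower, with GBP5 and GBP2 higher by 2.35 and 1.93, and of 17 stress genes 2 were higher and 2 lower. Of the MHC class II list 9 of 11 genes were lower, among them CD74, the invariant chain, at -2.03 ± 0.30 (SE). HLA-DRA was lower at -1.65 ± 0.55 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.0289), a call lost without library 2, at -1.57, and without library 5, at -1.43. Without library 1 the genes higher in T-like cells were 19, and without library 4 they were 49.

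B-like cells were higher in 24 and lower in 7 genes (24 and 9 adjusted over the list alone), and all 11 MHC class II genes were among the higher. HLA-DQA1 was higher by a log2 difference of 4.20 ± 0.35 (SE, n = 4 libraries), CIITA, the master regulator of the class II genes, by 3.84 ± 0.36 (SE), and HLA-DRA by 3.70 ± 0.49 (SE). HLA-DRA stood at 4313 ± 1466 CPM (SD, n = 4) in B-like cells and at 304 ± 267 (SD, n = 5) in T-like cells. TNF was higher by 4.48 ± 0.41 (SE; called under 16 of 16 alternatives, at 3.19 to 5.70) and stood at 302 ± 172 CPM (SD, n = 4), against 136 ± 76.5 (SD, n = 5) in T-like cells. In plasma-like cells of libraries 1 to 4 TNF stood at 3.52, 0, 3.34 and 76.1 CPM. A TNF UMI was seen in 15.3% of 983 B-like cells at a median of 1394 UMIs, and in 0.960% of 1042 plasma-like cells at the greater median of 1946.5. Of the homing list 6 of 9 genes were higher, with CCR7 at 2.94, CXCR4 at 2.74, ITGA4 at 1.90 and ITGB7 at 1.47, a call that ITGB7 lost without library 2, at 1.12. CD69, an early activation marker, was the 1 higher gene of the activation list, by 3.03. TNFRSF4, a costimulatory receptor of T cells, was lower at -2.93, a call lost without library 3, at -2.30, and without library 4, at -3.71. Of 9 interferon-stimulated genes 3 were higher, IFIT2 at 1.82, MX1 at 1.05 and ISG20 at 0.93. ISG20 lost its call without each of libraries 1, 2 and 3, at 1.03, 0.89 and 0.93, and MX1 without library 2, at 0.82. No type 1 or type 17 gene was called by edgeR's quasi-likelihood test (0 of 4 and 0 of 2, with 1 and 2 at an unadjusted p under 0.05, 0 and 2 lower adjusted over the list alone, and 0 and 0 by DESeq2). The lower genes were 3 without library 1, 1 without library 3 and 3 without library 4.

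Plasma-like cells were higher in 16 and lower in 8 genes, by both adjustments. CD38, a surface enzyme of antibody-secreting cells, was higher by a log2 difference of 3.74 ± 0.45 (SE, n = 4 libraries), CD27, a receptor of memory B and plasma cells, by 3.62 ± 0.38 (SE), and ITGB7 by 2.01 ± 0.41 (SE). The stress and dissociation list gave 11 of its 17 genes higher and 0 lower. Among them the heat-shock genes HSPA6, HSPA1B and HSPA1A were higher by 2.99, 2.36 and 1.92, the latter pair being close paralogues, and JUN by 1.82. The interferon-induced GTPase genes GBP2 and GBP1 were lower at -3.62 and -2.90, and the integrin gene ITGA1 was lower on 3 UMIs. Immunoglobulin RNA takes part of these cells' UMIs, and with immunoglobulin genes left out of all classes the calls were 152 in place of 148, 146 of them shared. The higher genes were 8 without library 1, and the lower genes were 3 without library 1 and 17 without library 4.

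Endothelial-like cells were higher in 9 and lower in 21 genes (9 and 22 adjusted over the list alone). S1PR1, the sphingosine receptor that ozanimod targets and that holds vessel barriers tight, stood at 378 ± 344 CPM (SD, n = 4; 826 in library 5 and at most 464 elsewhere) against 48.0 ± 45.8 (SD, n = 5) in T-like cells and 0 in fibroblast-like cells (edgeR, Benjamini-Hochberg adjusted p = 1.52e-09). CXCL9 stood at 174 ± 132 (SD, n = 4) and passed edgeR's test (Benjamini-Hochberg adjusted p = 8.63e-06), but not DESeq2's Wald test. ITGA1 was higher by a log2 difference of 3.32 ± 0.51 (SE, n = 4 libraries), HLA-DRB1 by 1.39 ± 0.37 (SE) and CD74 by 1.10 ± 0.28 (SE). HLA-DRB1 shares much of its sequence with HLA-DRB5, and reads of the pair are hard to part. Scrublet called 11.0% of the endothelial-like cells as doublets, the highest share of the tested classes, against 0.916% of B-like cells. These doublets stayed in the fit. With called doublets removed and cells clustered anew, library 2 had too few endothelial-like cells for a profile. Lower genes took in 10 of the 17 stress genes, such as DNAJB1 at -2.37, and CD69 and ITGA4 at -3.50 and -3.16. MADCAM1, the ligand of the integrin made by ITGA4 and ITGB7, stood at 304 ± 459 CPM (SD, n = 4; 987 in library 5 and at most 160.0 elsewhere) and had too few UMIs to test. The higher genes were 4 without library 1 and 18 without library 4, and the lower genes 12 without library 1 and 13 without library 2.

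Fibroblast-like cells were higher in 8 and lower in 12 genes (8 and 14 adjusted over the list alone). ITGA1, a collagen-binding integrin chain, was higher by a log2 difference of 3.16 ± 0.63 (SE, n = 3 libraries), the early-response gene EGR1 by 1.18 and NR3C1, the glucocorticoid receptor that steroid drugs act on, by 1.04. These calls were lost for ITGA1 without library 2, at 1.67, for EGR1 without library 4, at 0.66, and for NR3C1 without library 5, at 0.60. CD74 was lower at -1.88 ± 0.39 (SE) and GBP5 at -3.63 on 3 UMIs. BATF, a transcription factor of activated lymphocytes, was called lower on 1 UMI, so its fitted fold depends on the prior count. No type 1 or type 17 gene was called in endothelial-like or fibroblast-like cells by edgeR's quasi-likelihood test (0 of 4 and 0 of 2 in each class, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone; DESeq2 called 1 type 1 gene in endothelial-like cells and 0 elsewhere). Without library 4 the higher genes were 5, and without library 5 the lower genes were 6.

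Macrophage-like or monocyte-like cells held RNA of IL1B, IL8, PTGS2, IL1RN and OSM, but too few libraries held 20 of these cells for a test. IL1B, the inflammasome cytokine, stood at 4847 ± 1603 CPM (SD, n = 4 libraries), with a UMI in 65.9% of 85 cells at a median of 1808 UMIs against 0.293% of 1024 T-like cells at a median of 1403. IL8, the neutrophil chemokine now named CXCL8, stood at 2597 ± 2993 (SD, n = 4; 7025 in library 2 and at most 1768 elsewhere) and PTGS2, the inducible cyclooxygenase, at 934 ± 607 (SD, n = 4). IL1RN, the antagonist of the IL-1 receptor, stood at 821 ± 501 (SD, n = 4), and OSM, a cytokine that acts on gut stroma, at 239 ± 215 (SD, n = 4; 529 in library 2 and at most 270.3 elsewhere). TNF stood at 128, 570.4, 58.0 and 67.6 CPM in these cells of libraries 1 to 4. Only 1 of the 20 inflammatory mediators, TNF, had enough UMIs to test: it was higher in B-like and T-like cells and edgeR did not call it in fibroblast-like or plasma-like cells, though DESeq2's Wald test called it lower in the latter. TNF was also called lower in endothelial-like cells, but these held 1 TNF UMI in all, so the fitted fold depends on the prior count, and the call was lost without each of libraries 1, 2, 3 and 4. Fibroblast-like cells likewise held 1 TNF UMI, so the sizes of the TNF folds in B-like and T-like cells rest in part on such low counts.

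**Figure D2:**
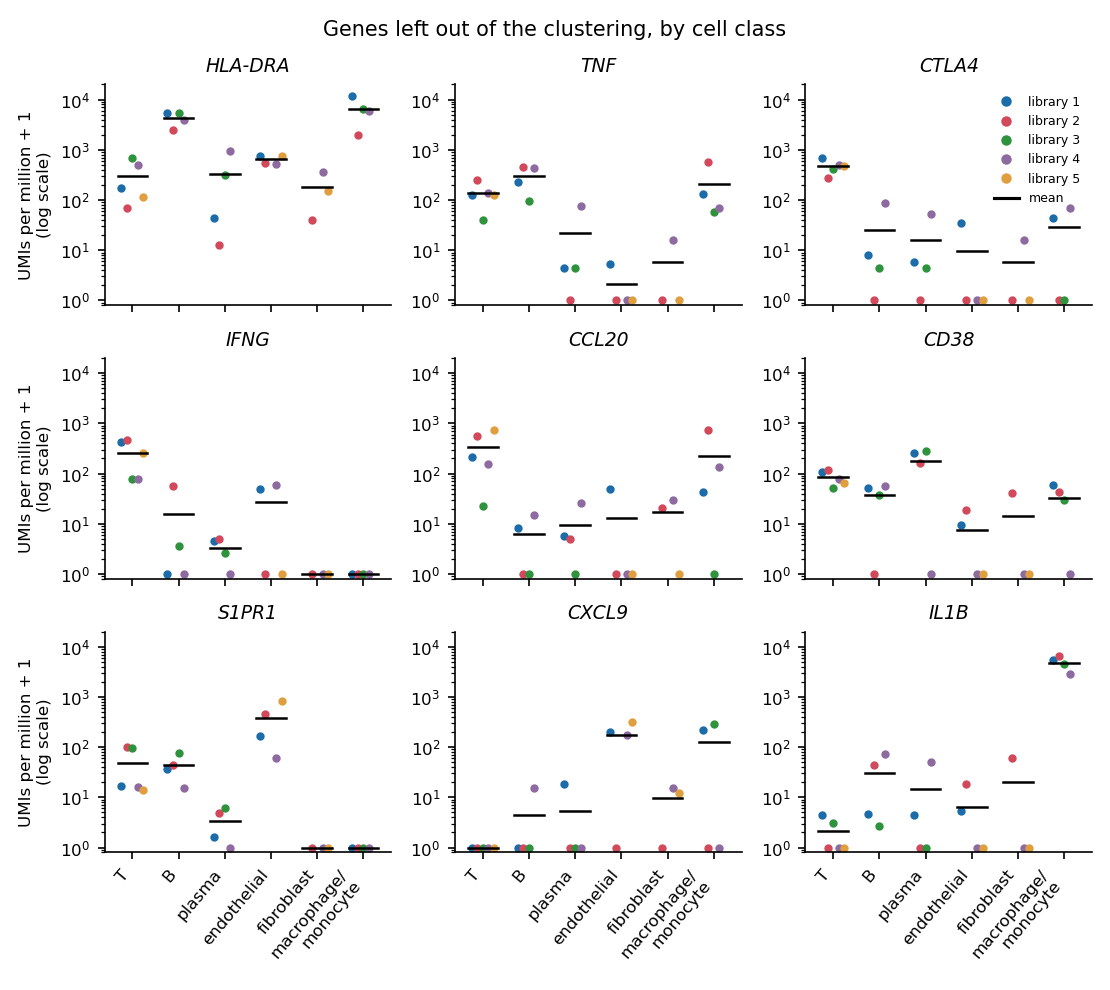
CPM plus 1 (vertical axis, log scale) of genes left out of the clustering, by cell class (horizontal axis); points are libraries with at least 10 cells of the class, and black lines are means. HLA-DRA has a mean of 4313 in B-like and 304 in T-like cells, CTLA4 of 467 in T-like cells and IL1B of 4847 in macrophage-like or monocyte-like cells.

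T-like cells with a KLRB1 UMI held more RNA of RBPJ, the DNA-binding effector of Notch signals, of MAF and RORA, transcription factors of helper T cell programmes, and of CTSH, a lysosomal protease, than T-like cells without a KLRB1 UMI that were matched on depth. They held less of ANXA1, a lipid-binding protein that curbs inflammation, and of CD55, which shields cells from complement. In libraries 1, 3 and 5, with 74, 80 and 34 cells on each side, median UMIs were 1821.5, 1855.5 and 1012.5 with a KLRB1 UMI and 1800, 1853.5 and 866 without, so library 5 was matched in part only. There edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 9 genes higher and 8 lower among 3110, and 265 had an unadjusted p under 0.05. RBPJ was higher by a log2 difference of 1.48 ± 0.26 (SE, n = 3 libraries; edgeR, Benjamini-Hochberg adjusted p = 0.000217), and MAF by 1.28 ± 0.25 (SE; adjusted p = 0.00167). CTSH, PTPN13 and TRPS1 were higher by 2.13, 2.06 and 1.83, NEDD9, KIAA0319L and RORA by 1.46, 1.44 and 1.04, and SLA by 0.93, each in 3 of 3 libraries. ANXA1 was lower at -1.40 ± 0.20 (SE; edgeR, Benjamini-Hochberg adjusted p = 3.30e-06), and CD55 and FAM65B at -1.56 and -1.44, in 3 of 3 libraries. The plasma cell genes IGKC, IGHG1, MZB1, XBP1 and IGHA1 were lower at -2.24, -1.99, -1.67, -1.37 and -1.30, in 2 of 3 libraries, and the immunoglobulin genes among them were named after their values were seen. With T-like cells of at least 10 heavy-chain UMIs left out, IGHG1 turned to 0.02 and IGKC to 0.61, and the calls fell to 3 higher and 3 lower (202 at an unadjusted p under 0.05), all 6 among the 17. All calls ended without library 1 (0, with 143 at an unadjusted p under 0.05), where the folds of 15 of the 17 genes kept their direction: RBPJ had 1.92, MAF 1.76, RORA 1.27, CTSH 3.05, PTPN13 2.71, TRPS1 2.35, NEDD9 1.58, KIAA0319L 1.35, SLA 1.15, CD55 -1.79, FAM65B -1.32, ANXA1 -1.14, XBP1 -1.20, IGHG1 -1.99 and IGKC -3.14, while MZB1 and IGHA1 had too few UMIs to test. Calls also ended without the library block (0, with 65), and DESeq2's Wald test gave 0 higher and 3 lower, with 54. Without library 3 the calls were 2 higher and 11 lower: RBPJ and ANXA1 kept theirs, and MAF (0.84), RORA (0.87), CTSH (1.87), PTPN13 (0.99), TRPS1 (1.45), NEDD9 (1.32), KIAA0319L (1.19), SLA (0.62), CD55 (-1.25), FAM65B (-1.68), MZB1 (-1.69) and XBP1 (-1.12) lost theirs. Without library 5 they were 14 and 13, and IGKC (-2.28) lost its call.

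None of the 64 tested genes of the held-out lists passed this test by edgeR over all genes (0, with 16 at an unadjusted p under 0.05, and 0 by DESeq2). CTLA4 had a log2 difference of 0.80 ± 0.23 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.0815), PDCD1 of 1.37 (adjusted p = 0.116) and TNF of 0.94 (adjusted p = 0.610). CD8A had a log2 difference of -0.91 (adjusted p = 0.140) and CD4 of 0.75 (adjusted p = 0.312), neither called, so a different mix of CD8 and CD4 T cells on the 2 sides is not excluded. The activation and checkpoint list had 11 of 13 genes on the positive side, 6 of them called higher when adjusted over the list alone, and was raised as a set by camera with a preset correlation of 0.01 (Benjamini-Hochberg adjusted p = 4.06e-05; adjusted p = 0.288 with an estimated correlation). Drug targets were also raised by camera with the preset correlation (adjusted p = 0.00273; adjusted p = 0.288 with an estimated correlation; 2 genes called adjusted over the list alone). Lowered sets with the preset correlation were the mitochondrial genome (adjusted p = 0.0014), the unfolded protein response (adjusted p = 0.00273), the cell cycle (adjusted p = 0.00273) and MHC class II (adjusted p = 0.00353). The unfolded protein response list holds XBP1, which was lower together with the plasma cell genes, at -1.37. Without the T-like cells of at least 10 heavy-chain UMIs XBP1 had -0.11. None of the 6 raised or lowered sets kept its call with an estimated correlation: the lowest value was adjusted p = 0.288 with an estimated correlation, and fry gave 0 calls with a lowest adjusted p = 0.315. The lists of T markers (adjusted p = 0.0566), stress (adjusted p = 0.227), plasma cell maturation (adjusted p = 0.230), homing (adjusted p = 0.316), oxidative phosphorylation (adjusted p = 0.548), type 1 effectors (adjusted p = 0.794) and interferon-stimulated genes (adjusted p = 0.997) were not called by camera. Adjusted over the list alone, 2 genes each of the cell cycle, MHC class II and unfolded protein response lists were lower. The interferon-stimulated list had a median log2 difference of -0.28 while camera's direction for it was upward, and the type 1 list a median of -0.04, a mean of 0.05 and a downward direction.

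**Figure D3:**
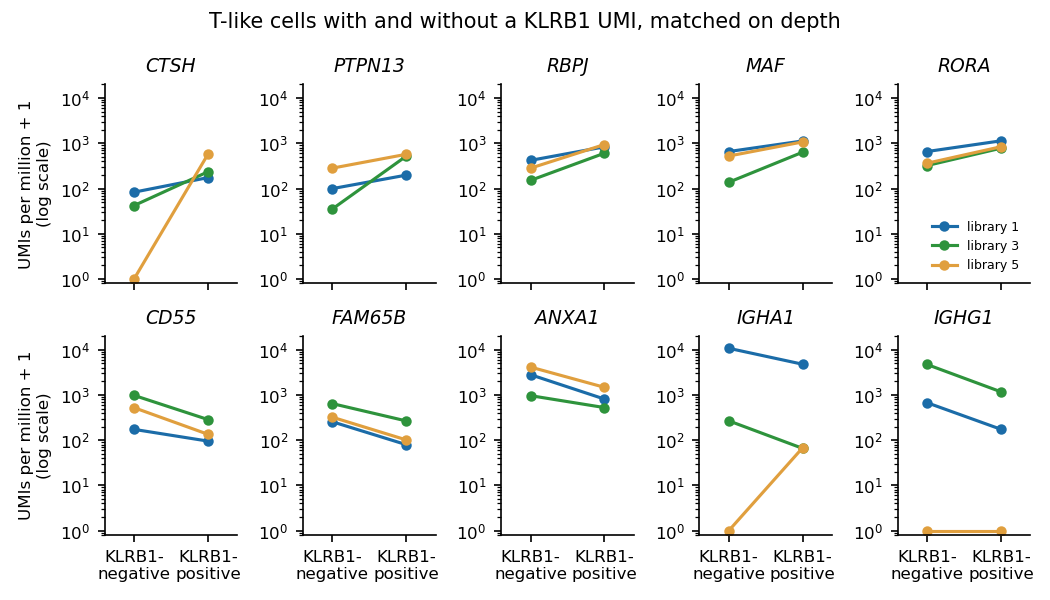
CPM plus 1 (vertical axis, log scale) of called genes in depth-matched T-like cells without and with a KLRB1 UMI (horizontal axis); each line joins the values of 1 of the 3 libraries. RBPJ is higher with a KLRB1 UMI in 3 of 3 libraries and ANXA1 lower in 3 of 3, whereas IGHA1 is lower in 2 of 3.

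Plasma-like cells with IgG held less RNA than those with IgA of CALR, a chaperone of the endoplasmic reticulum, and of DERL3 and EDEM3, which help clear misfolded proteins, and more of HLA-DRB1. Each of these calls was lost without library 1. In libraries 1, 2 and 3 edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 3 genes higher and 8 lower with IgG among 3905, each in 3 of 3 libraries, and 236 had an unadjusted p under 0.05. CALR was lower at a log2 difference of -1.08 ± 0.18 (SE, n = 3 libraries; edgeR, Benjamini-Hochberg adjusted p = 6.65e-06), EDEM3 at -0.94, NEU1 at -0.88, DERL3 at -0.80, MAPKAPK2 at -0.78 and VIM at -0.75. In this fit the SE and p rest on a spread shared over genes, and a gene's own spread between the 3 libraries hardly enters. DERL3 lost its call without each of libraries 1, 2 and 3, at -1.02, -0.55 and -0.92, as did EDEM3 at -1.14, -0.86 and -0.91, NEU1 at -1.55, -0.45 and -0.94, and MAPKAPK2 at -1.05, -0.61 and -0.79. PTPN18 was higher by 1.46 ± 0.36 (SE), HLA-DRB1 by 1.34 ± 0.32 (SE) and APOL6 by 0.77 ± 0.20 (SE). Calls were lost without library 1 for CALR (-1.09), HLA-DRB1 (1.39), APOL6 (1.17) and VIM (-0.63), without library 2 for APOL6 (0.51), and without library 3 for HLA-DRB1 (1.14), PTPN18 (1.47), APOL6 (0.79) and VIM (-0.68). ENAM, the gene of a tooth enamel protein, was lower at -3.64 ± 0.27 (SE; edgeR, Benjamini-Hochberg adjusted p = 4.36e-36) and kept its call under every alternative run. In the GRCh37 annotation ENAM lies on chromosome 4 at 71494461 to 71512541, close to the gene of the antibody J chain at 71521258 to 71547534 on the other strand. AL928768.3, a long non-coding RNA annotated on chromosome 14 at 106170301 to 106170939, lies over IGHA1 on the same strand and was lower with IgG at 3.50, 0 and 0 CPM against 176, 817 and 341 with IgA (edgeR, Benjamini-Hochberg adjusted p = 2.41e-35). It was named after its values were seen. Without library 1 and without the library block the calls were 0 higher and 2 lower (101 and 75 at an unadjusted p under 0.05), as by DESeq2's Wald test (42), and without library 3 they were 1 and 3. The 2 lower calls left without library 1 were ENAM and AL928768.3.

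Of the unfolded protein response and secretion list 15 of 16 genes lay on the lower side with IgG, 2 of them called when adjusted over the list alone, and camera lowered the set with a preset correlation (Benjamini-Hochberg adjusted p = 8.88e-08; adjusted p = 0.424 with an estimated correlation). Camera also lowered the plasma cell markers (adjusted p = 0.000138) and the mitochondrial genome (adjusted p = 0.000138) and raised MHC class II (adjusted p = 0.00527). None of the 4 calls held with an estimated correlation, and fry's directional test gave 0 calls with a lowest adjusted p = 0.369. Fry's mixed test, which disregards direction, called 3 lists: interferon-stimulated genes, MHC class II and plasma cell markers (adjusted p = 0.0422 for each). Camera did not call the lists of homing genes (adjusted p = 0.0558), B markers (adjusted p = 0.110), drug targets (adjusted p = 0.233), interferon-stimulated genes (adjusted p = 0.233), oxidative phosphorylation (adjusted p = 0.246), stress (adjusted p = 0.769), plasma cell maturation (adjusted p = 0.974) or activation (the highest adjusted p of the 12 lists). The stress list had a median log2 difference of 0.02 and the plasma cell maturation list a mean of 0.02, while camera's direction for both was downward. PDIA4, a disulfide isomerase, had a log2 difference of -0.68 (edgeR, Benjamini-Hochberg adjusted p = 0.0548), and TNFRSF17, the survival receptor BCMA, of -0.80 (adjusted p = 0.106).

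IgG and IgA divided the plasma-like cells in unequal parts from library to library. IgA, the secreted isotype of mucosal surfaces, was the main heavy chain of 42.9% ± 21.8 of plasma-like cells with at least 10 heavy-chain UMIs (SD, n = 4 libraries), IgG, the main isotype of serum, of 53.8% ± 22.7 (SD, n = 4) and IgM of 2.03% ± 0.520 (SD, n = 4). IgA made up 69.5% of 715 cells in library 1 (95% Clopper-Pearson interval 66.0 to 72.9) and 16.2% of 185 cells in library 3 (11.2 to 22.3). Cells without an isotype at 80% of their heavy-chain UMIs made up 1.29% ± 1.35 (SD, n = 4; 3.08% in library 1 and at most 1.56% elsewhere). T-like cells, which make no antibody, held medians of 1, 1, 1 and 0 heavy-chain UMIs in libraries 1 to 4, against 209, 500, 615 and 66.5 in plasma-like cells. When clusters with as many markers of another class kept their name, the IgM share was 8.29%, because library 5 entered with 2 of 6 cells, while libraries 1 to 4 did not change.

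**Figure D4:**
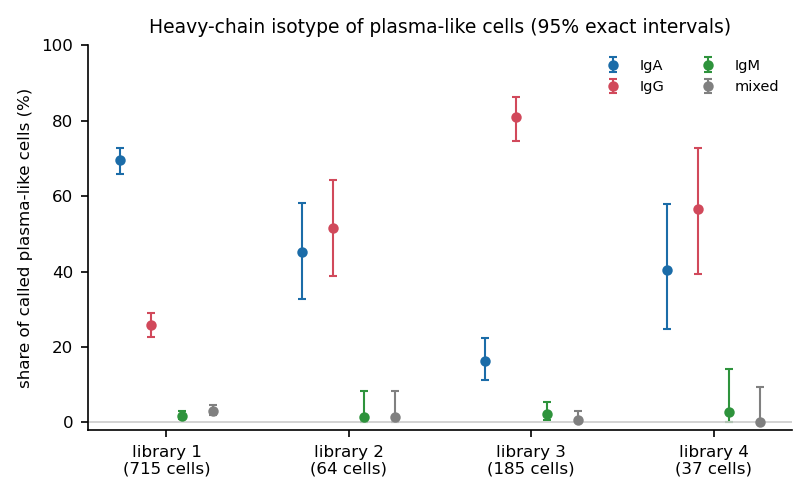
Share of plasma-like cells with a called isotype (percent, vertical axis) in libraries 1 to 4 (horizontal axis); points are isotypes and whiskers are 95% Clopper-Pearson intervals. IgA spans 16.2% in library 3 to 69.5% in library 1, and IgG 81.1% to 25.7%.

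HLA-DRA and CD38, classical activation markers of T cells, were seen together in few T-like cells, and no link between them was detectable at this depth. The mean log odds ratio of a UMI of both, within deciles of UMIs per cell, was -0.211 ± 0.548 (SD, n = 5 libraries), positive in 1 of 5, with a two-sided exact sign-flip p = 0.438 where 0.0625 is the smallest the design can give. T-like cells with both numbered 5 of 328, 1 of 23, 9 of 469, 0 of 124 and 0 of 80, with exact Clopper-Pearson upper bounds of 2.93% and 4.51% in the latter pair. With 0 such cells libraries 4 and 5 could not give a positive value, and theirs, -0.773 and -0.223, depend on the added 0.5. The 1 positive value, 0.693 in library 2, rests on 1 such cell and likewise depends on the added 0.5. Independence would give 5.5 cells in library 1 and 7.83 in library 3. Without UMI strata the mean log odds ratio was -0.0258, positive in 2 of 5 (exact sign-flip p = 0.875). HLA-DRA was seen in 16.5% of T-like cells at a median of 1403 UMIs, and in 10.3% of fibroblast-like cells at a median of 993; CD38 was seen in 0.641% of the latter. With cells thinned to 500 UMIs the mean log odds ratio turned to 0.186 (exact sign-flip p = 0.5), and within deciles it was -0.437 without library 2 and -0.0708 without library 4.

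IL17A, the cytokine that names the type 17 programme, was seen in T-like cells above the level of other cells, and its link to KLRB1 was not resolved. A UMI was seen in 7.03% of 1024 T-like cells at a median of 1403 UMIs and in 0.745% of 2955 other cells at a median of 1571. Library 1 held 51 of the 72 T-like cells with a UMI, and without it the share was 3.02% of 696 T-like cells, against 0.327% of 1529 other cells; without library 3 it was 11.5% of 555, against 0.953% of 2098. Its level in T-like cells was 119 ± 137 CPM (SD, n = 5), from 16.9 in library 2 to 343 in library 1. T-like cells with a KLRB1 UMI exceeded matched cells without by 58.9 ± 110 CPM (SD, n = 5), in 4 of 5 libraries (two-sided exact sign-flip p = 0.312). In libraries 2, 3 and 4 the excess rested on 1 against 0, 3 against 2 and 2 against 0 IL17A UMIs. In library 1 an IL17A UMI was seen in 13 of 74 cells on each side. Library 2 was matched in part only, at medians of 3313.5 and 2488 UMIs. The mean difference was 19.4 without library 4 and 92.3 without library 5. Against all T-like cells without a KLRB1 UMI it was 33.9 ± 103 (SD, n = 5), positive in 3 of 5 (exact sign-flip p = 0.625). KLRB1 was seen in 22.6%, 34.8%, 17.1%, 12.9% and 42.5% of the T-like cells of libraries 1 to 5, and in 0.644%, 0, 0.488%, 2.53% and 10% of their B-like and plasma-like cells.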

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

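The gap rule for single libraries was fixed before the data were examined, whereas the tests of TNF by doublets, markers of other classes and free RNA, of IGHG1 and IGHA by doublets and free RNA, and the counts of other splits were chosen after the results were seen.

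In 13 of 103 series of library values the highest library stood apart from the rest, by a gap to its nearest neighbour that took up most of the whole range. The rule would set apart about 1 in 20 series by chance if values were normally distributed. Shares and CPM cannot fall below 0, and series from the same library and class are not independent. The 13 of 103 thus cannot be read against that rate. NK-like cells made up 5.30% of library 1 and 0 of the other libraries (gap over range 1), where 4, 3 and 3 cells of libraries 2, 3 and 4 from the same cluster were too few to be named, and macrophage-like or monocyte-like cells 13.2% of library 2, with 3.79% next (0.761). In T-like cells IL22 stood at 693 CPM in the highest library and 71.7 in the next (0.896), FOXP3 at 274 and 63.7 (0.767) and CCR7 at 630.0 and 182 (0.770). In B-like cells TNFRSF4 stood at 56.6 and 0.85 CPM (0.985), ITGA1 at 56.6 and 3.56 (0.937) and IER3 at 156 and 32.9 (0.839). In endothelial-like cells CD27 and TNF each stood at 4.32 CPM and 0 (gap over range 1 for each), which is 1 UMI of each gene in 1 library, ITGA4 at 58.5 and 22.9 (0.863), GBP2 at 739 and 234 (0.962) and DNAJB1 at 2748 and 696 (0.842). What set these libraries apart was not tested, and the labels give no group or batch that parts them.

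TNF was higher in B-like cells by a log2 difference of 4.48 ± 0.41 (SE). Removal of called doublets, after which cells were clustered and named anew, left TNF at 3.63 but decides nothing, since it took 0.916% of the B-like cells and changed their naming too. Doublets with cells of another class were argued against as the whole cause by the markers of those classes: at the level at which these stood in B-like cells, the other classes would bring at most 7.19% of the TNF in any of 4 libraries. Free RNA was argued against too: in libraries 1 and 3 the share of B-like cells with a TNF UMI, 17.4% and 12.8%, exceeded the upper bound of the plasma-like share, 1.58% and 3.83%, by at least 8.95 percentage points, though plasma-like cells were deeper. Induction of TNF by thawing or digestion stays open, since no undigested tissue was measured, and no biological explanation was tested because the design holds 1 group.

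Plasma cell transcripts (IGHG1, IGKC, IGHA1, MZB1 and XBP1) were lower in T-like cells with a KLRB1 UMI. Removal of called doublets, with cells clustered and named anew, left IGHG1 at -1.46 but decides nothing, since it took 2.15% of the T-like cells and changed their naming too. Free RNA and these transcripts cannot be told apart: the IGHA part of IGHA and IGHG UMIs in KLRB1-negative T-like cells differed from that in plasma-like cells by 33.2 points in library 1 (89.3% and 56.1%) but stood at 2.50% and 10.5% in library 3, within the 15 points set, and 58.2% and 86.8% of these UMIs sat in the top 5% of cells. RNA from a few T-like cells with at least 10 heavy-chain UMIs, which may be uncalled doublets, stays open. Without them XBP1 went from -1.37 ± 0.30 (SE) to -0.11 ± 0.35 (SE), because its fold fell towards 0, and MZB1 had too few UMIs to test, so the pattern and these cells cannot be told apart.

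ENAM and AL928768.3 were lower in IgG than in IgA plasma-like cells. For ENAM the J chain gene nearby is a candidate source: ENAM per J chain UMI in IgG cells was 0.701 of that in IgA cells (95% interval 0.490 to 1.0), within the 2-fold range set for it. The lower bound of the interval fell just outside that range. Reads at ENAM may be J chain RNA, which IgA cells hold more of. The ratio cannot part such reads from ENAM RNA that varies along with J chain RNA, and the genes lie on opposite strands. For AL928768.3 the ratio to IGHA1 in cells outside the plasma-like class over that in IgA cells was 2.51 (1.85 to 3.40), an interval on both sides of the 2-fold limit set for it, so AL928768.3 and IGHA1 RNA cannot be told apart. No biological explanation was tested.

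For the comparison of classes 1 of 100 assignments of class names within libraries, the real one, gave as many as its 148 calls, and the highest of the others gave 8. The classes were clusters of the same cells' RNA, so fewer calls with shuffled names were bound to follow, and nothing is excluded by this count. For T-like cells with and without a KLRB1 UMI the 10 splits are too few for a share under 0.05. The real split gave 17 calls, the highest other 7, and the highest other of the 4 splits that part all pairs gave 6. For IgG against IgA the 10 splits are likewise too few, with 11 calls for the real split, 9 for the highest other and 0 for the highest other of the 4 that part all pairs.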

How the results depend on the processing

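Alternatives chosen only after the data were seen were those that left out immunoglobulin genes, T-like cells with at least 10 heavy-chain UMIs or libraries 4 and 5, and that named classes cell by cell or kept the names of tied clusters, while the set tests with an estimated correlation and fry were in the design and were set beside the preset correlation later. Unless a reason is given, the cause was not tested.

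Of the values for named genes in the class comparison (108 gene and class pairs) 1407 kept direction and side of the threshold, 196 lost the call and 3 reversed. For KLRB1 (82 genes) the counts were 1005, 93 and 3, with 11 newly past the threshold, and for IgG against IgA (55 genes) 534, 70 and 0, with 6 newly past it. Among counts, shares and single tests 287 were the same, 47 weaker, 21 stronger, 5 moved and 1 reversed. ENAM kept its call under all alternatives run, as did TNF in B-like and T-like cells.

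Without each library in turn, where fewer or other libraries enter, the calls per class ranged as follows: T-like 19 to 49 higher, B-like 1 to 9 lower, plasma-like 8 to 18 higher and 3 to 17 lower, endothelial-like 4 to 18 higher and 12 to 19 lower, fibroblast-like 5 to 10 higher and 6 to 17 lower. KLRB1 calls ranged from 0 to 14 higher and 0 to 13 lower, and IgG against IgA calls from 0 to 4 higher and 2 to 9 lower. Library 1 held the most plasma-like cells and UMIs, and without it the 0 higher and 0 lower KLRB1 calls by edgeR stood beside 143 genes at an unadjusted p under 0.05.

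DESeq2's Wald test gave 0 higher and 3 lower for KLRB1 (54 at an unadjusted p under 0.05) and 0 higher and 2 lower for IgG against IgA (42), while its class calls were 146, 135 of them shared with edgeR's. Without the library block edgeR gave 0 higher and 0 lower for KLRB1 (65), 0 and 2 for IgG against IgA (75), 5 lower for T-like, 9 lower for endothelial-like and 6 higher for plasma-like cells. With no low-count filter, which tests more genes, IgG against IgA gave 1 higher and 3 lower, KLRB1 23 lower, T-like 62 higher, endothelial-like 15 higher, fibroblast-like 13 higher and plasma-like 19 lower.

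Profiles of at least 10 cells gave IgG against IgA 0 higher and 3 lower, T-like 21 lower and plasma-like 17 lower. The filter of 300 genes and 500 UMIs in place of the authors' cells gave IgG against IgA 0 higher and 3 lower, KLRB1 2 higher and 3 lower with XBP1 turned to 0.28, B-like 12 lower, T-like 19 lower and plasma-like 27 lower. Removal of called doublets, after which cells were clustered and named anew so that 2 choices changed together, gave IgG against IgA 5 lower, KLRB1 16 higher, plasma-like 9 higher and 13 lower, and turned CD28 in B-like cells to 1.19, GBP1 in fibroblast-like cells to -0.047 and GZMA in plasma-like cells to 0.50. Leiden resolution 0.5 gave 11 lower for B-like and 13 lower for plasma-like cells, and 11.7% of cells unnamed. Classes named cell by cell left 12.3% unnamed. Without libraries 4 and 5 the calls were 13 lower for B-like and 35 lower for plasma-like cells.

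All KLRB1-negative T-like cells as the other side gave 4 higher and 4 lower, and for IL17A 33.9 ± 103 CPM (SD, n = 5; exact sign-flip p = 0.625). T-like cells with at least 10 heavy-chain UMIs left out gave 3 higher and 3 lower, with IGHG1 turned to 0.023 and IGKC to 0.61, which follows from leaving out the cells richest in heavy chains. An isotype purity of 95% raised mixed cells to 7.92%, by its own construction, at least 3 heavy-chain UMIs gave IgM in 2.56%, and tied clusters kept under their name gave IgM in 8.29%, as library 5 entered with 2 of 6 cells, and turned the plasma-like share of library 5 from 0.446% to 11.2%, a share that was 12.8% with called doublets removed and cells clustered anew, and 14.8% with the filter of 300 genes. T-like cells thinned to 500 UMIs turned the log odds ratio of HLA-DRA and CD38 to 0.186 (exact sign-flip p = 0.5). Camera with an estimated correlation gave 0 calls for KLRB1 and 0 for IgG against IgA, as fry's directional test did with 0 and 0, against 6 and 4 with the preset correlation. Fry's mixed test gave 0 for KLRB1 and 3 for IgG against IgA.

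The planned pairs of classes within the T and the myeloid lineage were not run, since none of them reached 20 cells on each side in 3 libraries. Depth limits libraries 4 and 5 most, at medians of 589 and 918 UMIs per cell, so genes seen as 0 there are not shown to be absent.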

Other observations

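The values here were noted after the data were seen and no explanation was tested. A cluster of 14 unnamed cells of library 1 was led by CHGA, SST, CHGB, TPH1, PYY and GCG, hormone and granule genes of gut endocrine cells. Another of 25 unnamed cells of library 1 was led by SH2D6, TRPM5, IL17RB, HPGDS and PTGS1, genes known from chemosensory tuft cells. CXCL1 stood at 666 ± 370 CPM in epithelial-like cells (SD, n = 2 libraries; 928 in library 1 and 404 in the other) and at 313 ± 393 in fibroblast-like cells (SD, n = 3; 765 in library 4 and at most 114 elsewhere). IL23A stood at 63.0 ± 41.3 CPM in T-like cells (SD, n = 5) and at 69.9 ± 112 in macrophage-like or monocyte-like cells (SD, n = 4; 236 in library 2 and at most 29.0 elsewhere). IL26, a further type 17 cytokine, stood at 42.4 ± 34.1 CPM in T-like cells (SD, n = 5).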
